A study of Mus musculus with 12 samples.

How the data were processed

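Gene expression was measured in follicular B cells sorted from the spleens of 8-week-old male 129SvEv mice, wild type or labelled Zfx cko, and cultured with 10 µg/mL of anti-IgM for 0, 2 or 12 h. The gate was set on B220, AA4.1, CD23 and CD21. Per the labels' protocols, 100 ng of RNA was amplified in 2 rounds, 10 µg of amplified RNA was put on each array, and labelled RNA was hybridized in duplicate to whole-genome mouse arrays with spike-in controls. Per the submitters' processing notes the arrays were summarised with GCOS 1.4. The deposited values are linear signal intensities, 1 per probe set and array, and the mean without the top and bottom 2% of probe sets was 250 on each of the 12 arrays, as checked on the values. The summarisation algorithm and detection calls are not given in the sources used here. The 12 columns fell into 6 groups of 2 arrays by genotype and time, and 0 columns were left unassigned.

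Signals were transformed as log2(signal + 16) with no further normalization. Of 45101 probe sets, 64 were controls, 9160 had no gene symbol and 932 had several, and these were left out of the gene tests. Of the 34945 with 1 symbol, 99.4% matched the mouse RefSeq table by Entrez identifier. Probe sets with a mean at or under the 40th percentile (5.14 on the log2 scale) were left out, which left 21906. Each gene was represented by its probe set with the highest mean, which gave 12190 genes, 5567 of them with several probe sets. Genomic coordinates of the probe sets were not analysed here.

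The genes were tested with limma 3.58.1 in R 4.3.3, with 1 mean per group on all 12 arrays (6 residual degrees of freedom, 7.3 prior degrees of freedom) and eBayes with an intensity trend. There were 10 contrasts, namely cko against wild type at each time and as the mean over the 3 times, 2 h and 12 h of anti-IgM against 0 h in each genotype, and the interaction of genotype with each response. Tests were two-sided, p was adjusted by Benjamini-Hochberg over the 12190 genes of a contrast, and a gene was called at an adjusted p under 0.05. The words rose, fell, higher and lower are used of called genes. The group comparisons rest on 2 arrays per group, and their number limits precision.

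Of 33 gene lists written from general knowledge (673 entries, 585 of them tested), 31 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Counts of members adjusted over the list alone use the same p-values adjusted within the list. At the preset correlation 83 list calls were made over all contrasts, and 23 of them held with an estimated correlation. Some lists share genes. Not every list is described one by one, and those described include some without a call or with a call lost under several alternatives.

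The lists, the contrasts, the tests, most alternatives and the rule for naming genes were chosen before the data were examined. In each contrast the rule takes the 8 largest rises and the 8 largest falls among called genes whose groups do not overlap, and for the mean and interaction contrasts it drops the overlap condition. It takes the 4 members with the smallest p of each list described. Zfx, Zfy1, Zfy2, Ccnd2, Bcl2l1, Ddit3, Trib3, Atf4, Asns, Myc, Egr1, Bcl2l11, Cdkn1a, Mcl1, Cd69, Cd86 and Xist are always named. Predicted genes, Riken clones and immunoglobulin variable segments are not named among the largest changes, and for length members were left out from the smallest change up. Where fewer than 3 genes pass in a direction, the 3 with the smallest p are given as not passing.

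The procedure was tested on simulated data with the dimensions of this study, with steps in 200 of 12190 genes of the comparison of the genotypes at 2 h. It recovered 24% of genes with a log2 step of 0.5, 68% at 1, 98% at 2 and 58% at -1, with 6 false calls and 0 calls in the unchanged contrasts. The list that was shifted was called and 0 other lists were. The simulated genes varied independently of each other, with the residual spread of the real arrays and no difference between sets of arrays. False list calls from correlated genes could thus not appear. The real contrasts called 20.4 to 63% of the genes, so the rates above do not carry over to them.

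The alternatives tried were quantile normalization, median scaling, pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, eBayes without a trend, array weights, only the groups compared, the replicate number as a block, every probe set, the mean of a gene's probe sets, each array left out in turn and a size threshold of 2-fold. Without an array, 1 group keeps a lone array that is assumed to vary like the other groups. Added after the data were examined were a term for the control-probe division, the mean of duplicate arrays and the mean genotype difference without 12 h. Control probe sets for 18S ribosomal RNA, actin, Gapdh and the spike-ins were read on each array and not used in the tests. Replicate numbers of different groups did not pair, as correlations of the residuals over the 15 pairs of groups ran from -0.014 to 0.013. Not analysed here were probe-level files and the genotype of the mice.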

Results

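Follicular B cells were sorted from the spleens of male 129SvEv mice that were wild type or labelled Zfx cko, and were cultured with anti-IgM, an antibody that crosslinks the B cell receptor, for 0, 2 or 12 h. Their RNA was read on 12 whole-genome expression arrays, 2 for each of the 6 combinations of genotype and time. Each array held 45101 probe sets, from which 12190 genes were tested. The 2% trimmed mean of the signal was 250 on every array, and the median signal ran from 29.1 to 40.3. The number of arrays limits the precision of every value. Values in parentheses after a gene are log2 differences ± SE between groups of n = 2 arrays, unless another n is given. Per the labels' protocols each labelled RNA was hybridized in duplicate, and whether the duplicates came from different mice is not given in the sources used here. The p-values measure only the spread between these arrays, which may be technical.

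Duplicate arrays lay close together, with r from 0.983 to 0.989 across probe sets, which are not independent replicates. Principal component 1 held 53.4% of the variance and component 2 held 18.1%. Control probe sets divided the arrays into 2 sets of 6. In the wild-type 0 h, wild-type 12 h and cko 0 h groups, the 5′ signal of actin was 1.80 to 3.33% of its 3′ signal. In the wild-type 2 h, cko 2 h and cko 12 h groups it was 8.41 to 19.1%. The 18S ribosomal RNA 3′ signal was 6636 to 10892 in the former groups and 1022 to 1299 in the latter. The genotype comparisons at 0 h and at 2 h, the wild-type 12 h response and the interaction at 2 h lie within this division or balance it. The genotype comparison at 12 h, the 2 h responses, the cko 12 h response and the interaction at 12 h cross it. The mean genotype difference includes the 12 h comparison.

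**Figure D1:**
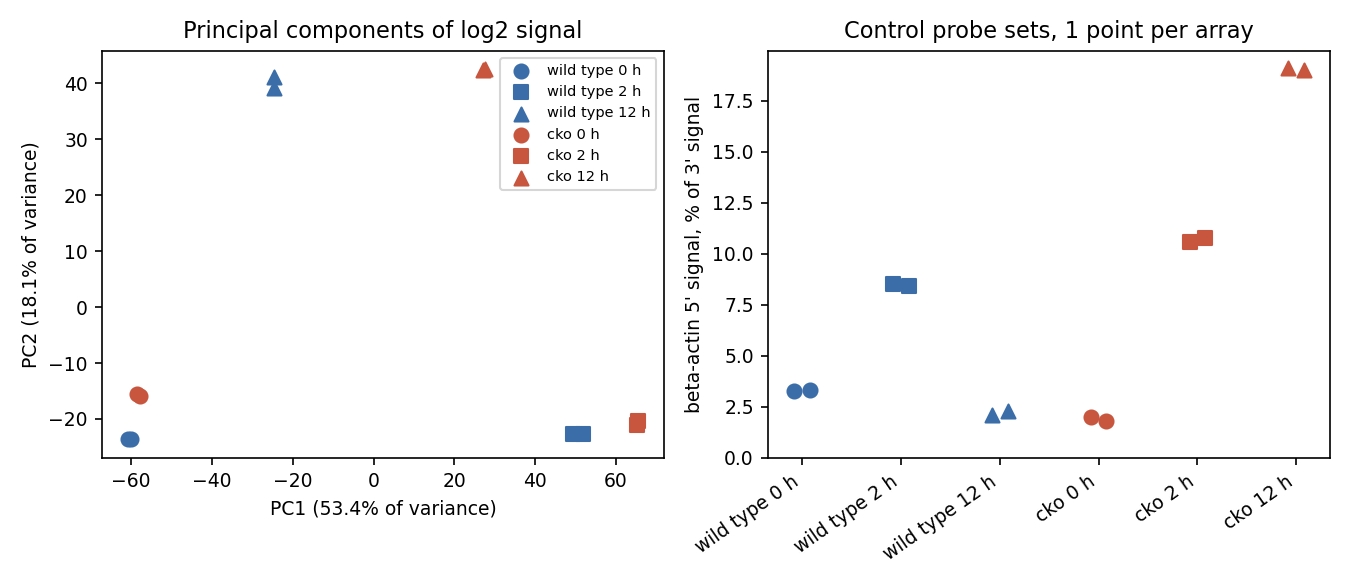
The left panel places the 12 arrays on principal components 1 and 2, and the right panel gives the 5′ signal of actin as a percent of its 3′ signal on each array. The wild-type 2 h, cko 2 h and cko 12 h arrays sit between 8.41 and 19.1%, and the other 6 arrays sit between 1.80 and 3.33%.

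Zfx itself, the zinc-finger transcription factor named in the labels, was read by 4 probe sets. The brightest was higher on the arrays labelled cko at all 3 times. At 0 h its signal was 1011.9 ± 41.6 in wild type and 2403 ± 304 in cko (SD, n = 2), a log2 difference of 1.23 ± 0.09. At 12 h the signals were 987.4 ± 35.5 and 1289 ± 73.6, a log2 difference of 0.38 ± 0.09. The difference at 2 h was 0.32 ± 0.09, from 799.6 ± 14.2 to 1004 ± 42.7, and it was no longer called without replicate 1 (0.34) or replicate 2 (0.30) of wild type or replicate 2 of cko (0.28). The mean of all probe sets of Zfx that passed the filter was not called in any genotype comparison, nor in the 2 h responses or the interactions. The other 3 probe sets had group means of 9.3 to 167.6 and were not called between the genotypes. The position of the deleted part, and of the probe sets relative to it, is not given in the sources used here, so these values do not check the genotype. Group means of Zfy2 signal were 3.0 to 14.2, and Zfy1 was not tested. Xist was tested on its only probe set that passed the filter, with group means of 33.7 to 107.2. Its other probe sets had group means of 1.1 to 19.4, and the mice were male. The calls on Xist below rest on the former probe set alone.

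The responses of wild-type cells to receptor crosslinking come first, as the background for the genotype. After 2 h of anti-IgM, the nuclear receptor gene Nr4a3 (6.10 ± 0.10) had risen the most, from a signal of 113.5 ± 17.5 to 8822 ± 170 (SD, n = 2). It was followed by the nucleolar gene Nop58 (5.28 ± 0.13), the secreted peptide gene Adm (5.26 ± 0.15) and the chemokine gene Ccl4 (5.0 ± 0.10). Xaf1 (-5.31 ± 0.18), Kbtbd11 (-5.19 ± 0.09) and Trp53inp2 (-4.70 ± 0.18) had fallen the most. The transcription factor genes Myc (3.55 ± 0.12) and Egr1 (2.59 ± 0.06), the cell cycle inhibitor Cdkn1a (2.92 ± 0.14), the costimulatory gene Cd86 (2.22 ± 0.07), the cyclin gene Ccnd2 (1.58 ± 0.06) and the survival gene Bcl2l1 (0.86 ± 0.17) rose. The pro-apoptotic Bcl2l11 (1.81 ± 0.11), the stress regulators Atf4 (1.64 ± 0.06) and Ddit3 (0.64 ± 0.09), Asns (0.61 ± 0.10) and Xist (1.09 ± 0.20, from a signal of 33.7 to 90.2) rose too, and the survival gene Mcl1 (-0.58 ± 0.05) fell. Trib3 (1.62 ± 0.53), Cd69 (0.22 ± 0.09) and Zfx (-0.33 ± 0.09) are given as values. The call on Trib3 was lost without replicate 2 of wild type at 0 h (0.91) or replicate 1 (1.67) or 2 (1.57) at 2 h, and that on Cd69 without the same arrays (0.16, 0.22 and 0.22). Trib3 was 2.32 without replicate 1 of wild type at 0 h. The call on Zfx was lost under median scaling (-0.14).

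Ribosome biogenesis genes rose almost without exception at 2 h in wild type. Of 28 tested, 27 rose and 1 fell, with a list median of 1.74 against -0.24 for all genes (adjusted p = 1.3e-13, and adjusted p = 0.0073 with an estimated correlation). Examples were Nop16 (3.60 ± 0.09), Gnl3 (2.39 ± 0.06) and Fbl (2.17 ± 0.06). Of 22 NF-kB target genes, 15 rose and 5 fell, among them Nfkbid (2.46 ± 0.07), Rel (2.45 ± 0.08) and Irf4 (1.92 ± 0.05) (adjusted p = 0.00022, and adjusted p = 0.16 with an estimated correlation). Of 26 immediate early genes, 16 rose and 9 fell, with Dusp4 (3.68 ± 0.12) and Nr4a1 (2.53 ± 0.06) among the rises (adjusted p = 0.0042, and adjusted p = 0.16 with an estimated correlation). Genes of the integrated stress response, the program of ATF4 and CHOP, gave 19 rises and 6 falls of 33, with the folate-cycle gene Mthfd2 (3.46 ± 0.09) and the amino acid transporter genes Slc7a5 (2.84 ± 0.14) and Slc7a1 (1.87 ± 0.06) in front (adjusted p = 0.0011, and adjusted p = 0.16 with an estimated correlation). Of 19 aminoacyl-tRNA synthetase genes, 14 rose and 5 fell, with Rars (3.0 ± 0.13), Tars (2.72 ± 0.07) and Vars (-2.53 ± 0.09) at the ends (adjusted p = 0.0094, and adjusted p = 0.18 with an estimated correlation). These counts were the same when adjusted over the list alone.

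Across all genes, 7277 of 12190 were called in wild type at 2 h, 2867 higher and 4410 lower, and 3724 of them moved at least 2-fold. The median of all genes was -0.24, and it was -0.04 under median scaling, which raised the share of called genes that were higher from 39.4 to 49.3%. The actin 5′ to 3′ ratio differed between these groups (3.30 ± 0.04% at 0 h and 8.46 ± 0.07% at 2 h, SD, n = 2). In all, 4708 genes were called in a model with the control-probe division as a term and 1 time effect for both genotypes.

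At 12 h in wild type Adm (4.18 ± 0.15), the cell cycle inhibitor Cdkn1a (4.13 ± 0.14) and the transcription factor Egr2 (3.89 ± 0.12) showed the largest rises. The immediate early gene Fos (-5.22 ± 0.07), the cytokine signalling inhibitor Socs3 (-4.56 ± 0.25), Trp53inp2 (-4.35 ± 0.18), the quiescence factor Klf4 (-4.25 ± 0.12) and the proliferation marker Mki67 (-3.98 ± 0.39) showed the largest falls. Bcl2l1 (2.05 ± 0.17) rose from a signal of 464.6 ± 32.2 to 1977 ± 283 (SD, n = 2). Ccnd2 (1.64 ± 0.06), Bcl2l11 (1.54 ± 0.11), Xist (1.31 ± 0.20, from a signal of 33.7 to 107.2), Asns (0.89 ± 0.10), Egr1 (0.83 ± 0.06) and Cd86 (0.63 ± 0.07) rose as well. Mcl1 (-0.22 ± 0.05), Atf4 (-0.29 ± 0.06) and the early activation marker Cd69 (-2.36 ± 0.09) fell. Myc (0.08 ± 0.12) was not called. Zfx (-0.03 ± 0.09) was called only with the mean of its probe sets (-0.49). Trib3 (0.77 ± 0.53) was not called with all arrays and was called without replicate 1 of wild type at 12 h (1.91) and with the mean of its probe sets (0.74). The call on Ddit3 (-0.34 ± 0.09) was lost without replicate 1 of wild type at 0 h (-0.28) or at 12 h (-0.19).

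Growth metabolism rose across several gene groups in wild type at 12 h, where the median of all genes was 0.03. All 28 ribosome biogenesis genes rose (list median 1.18, adjusted p = 1.2e-12, and adjusted p = 0.009 with an estimated correlation), Fbl (1.84 ± 0.06) and Noc4l (1.52 ± 0.06) among them. Of 31 oxidative phosphorylation genes, 28 rose and 1 fell, Ndufa5 (1.74 ± 0.08) and Ndufc1 (1.66 ± 0.05) in front (adjusted p = 1.6e-09, and adjusted p = 0.021 with an estimated correlation). Of 19 sterol biosynthesis genes, 17 rose and 0 fell, led by Idi1 (3.06 ± 0.13), Hmgcs1 (2.41 ± 0.05) and Sqle (2.11 ± 0.13) (adjusted p = 4.6e-08, and adjusted p = 0.011 with an estimated correlation). Of 15 glycolysis genes, 10 rose and 2 fell, with Ldha (1.5 ± 0.06) and Aldoa (1.37 ± 0.07) as examples (adjusted p = 0.0034, and adjusted p = 0.033 with an estimated correlation). Aminoacyl-tRNA synthetase genes gave 15 rises and 1 fall of 19, among them Aars (1.22 ± 0.09) and Mars1 (1.07 ± 0.08) (adjusted p = 0.00011, and adjusted p = 0.025 with an estimated correlation). Adjusted over the list alone, 11 glycolysis genes rose and 3 fell, 16 synthetase genes rose and 1 fell, and the other counts were unchanged.

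Genes of the resting follicular cell fell in the same comparison. Of 16 follicular identity genes, 13 fell and 0 rose, Klf2 (-3.16 ± 0.09), Cd55 (-1.94 ± 0.08) and Cd22 (-1.25 ± 0.05) among them (list median -1.27, adjusted p = 4.6e-08, and adjusted p = 0.016 with an estimated correlation). Of 11 MHC class II presentation genes, 10 fell and 0 rose, with H2-DMa (-2.43 ± 0.06) and H2-Oa (-2.32 ± 0.08) as examples (adjusted p = 2.1e-06, and adjusted p = 0.025 with an estimated correlation). Of 26 quiescence and cell cycle inhibitor genes, 18 fell and 3 rose, Tsc22d3 (-3.28 ± 0.11) and Klf4 among the falls and Cdkn1a among the rises (adjusted p = 1e-04, and adjusted p = 0.021 with an estimated correlation). Inhibitory receptor and phosphatase genes gave 12 falls and 1 rise of 16, with Siglecg (-2.21 ± 0.08) and Dok3 (-1.91 ± 0.08) in front (adjusted p = 0.00022, and adjusted p = 0.021 with an estimated correlation). Of 22 G2/M genes, 14 fell and 1 rose, Mki67 and Ube2c (-2.11 ± 0.27) among the falls (adjusted p = 3e-04, and adjusted p = 0.021 with an estimated correlation). Of 18 interferon response genes, 11 fell and 1 rose, Xaf1 (-2.18 ± 0.18) and Ddx58 (-2.05 ± 0.12) among the falls (adjusted p = 0.00022, and adjusted p = 0.025 with an estimated correlation). Genes listed as markers of other cells moved with them, as 13 of 19 myeloid markers fell and 0 rose, S100a9 (-2.03 ± 0.09) among them (adjusted p = 3.2e-06, and adjusted p = 0.025 with an estimated correlation). Similarly, 10 of 14 T and NK cell markers fell and 0 rose, Cd2 (-3.95 ± 0.11) and Cd3e (-2.92 ± 0.38) among them (adjusted p = 4.2e-05, and adjusted p = 0.021 with an estimated correlation). Counts adjusted over the list alone were 14 follicular genes, 15 G2/M genes and 15 myeloid markers lower and 2 inhibitory receptor genes and 2 G2/M genes higher, and the others were unchanged.

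In all, 5842 genes were called in wild type at 12 h, 3025 higher and 2817 lower, and 2068 moved at least 2-fold. The actin 5′ to 3′ ratio was 3.30 ± 0.04% at 0 h and 2.19 ± 0.11% at 12 h (SD, n = 2).

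On the cko arrays Nr4a3 (7.74 ± 0.10) rose the most after 2 h, from a signal of 34.5 ± 2.72 to 10784 ± 307 (SD, n = 2), followed by Nop58 (5.34 ± 0.13), Ccl4 (5.13 ± 0.10) and the pseudouridine synthase gene Pus7 (4.75 ± 0.16). Xaf1 (-5.17 ± 0.18), Gimap7 (-4.77 ± 0.10) and St3gal1 (-4.74 ± 0.18) fell the most. Myc (3.12 ± 0.12), Egr1 (3.06 ± 0.06), Cdkn1a (2.08 ± 0.14), Cd86 (2.03 ± 0.07), Atf4 (1.74 ± 0.06), Bcl2l11 (1.29 ± 0.11), Ccnd2 (1.05 ± 0.06), Bcl2l1 (1.0 ± 0.17), Asns (0.81 ± 0.10), Ddit3 (0.48 ± 0.09) and Cd69 (0.39 ± 0.09) rose. Mcl1 (-0.84 ± 0.05) and Zfx (-1.24 ± 0.09) fell. Xist (0.47 ± 0.20) was not called, but it was under quantile normalization (0.68) and median scaling (0.76). The call on Trib3 (1.43 ± 0.53) was lost without replicate 1 (1.39) or 2 (1.47) of cko at 0 h or replicate 1 (1.51) or 2 (1.35) at 2 h.

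Of 28 ribosome biogenesis genes, 27 rose and 0 fell in cko at 2 h, with Nop16 (3.76 ± 0.09) and Ncl (2.72 ± 0.07) behind Nop58 (list median 1.89 against -0.32 for all genes, adjusted p = 6.5e-14, and adjusted p = 0.0069 with an estimated correlation). Of 33 integrated stress response genes, 20 rose and 4 fell, Mthfd2 (2.66 ± 0.09) in front (adjusted p = 0.00038, and adjusted p = 0.12 with an estimated correlation). With p adjusted over the list alone, 21 rose and 5 fell. Of 26 immediate early genes, 16 rose and 6 fell, with Egr2 (3.83 ± 0.12) next to Nr4a3 (adjusted p = 0.00077, and adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone, 16 rose and 7 fell. In total 7684 genes were called, 2907 higher and 4777 lower, 4274 of them at least 2-fold, with a median of -0.32 over all genes that was -0.03 under median scaling. The share of called genes that were higher was 37.8%, and 51.1% under median scaling. The actin 5′ to 3′ ratio was 1.90 ± 0.13% at 0 h and 10.7 ± 0.14% at 2 h (SD, n = 2).

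At 12 h in the cko arrays Nop58 (4.56 ± 0.13), Nr4a3 (4.08 ± 0.10), the respiratory chain gene Uqcrh (4.06 ± 0.12) and the RNA export gene Alyref (3.87 ± 0.13) had risen the most. Fos (-6.11 ± 0.07), the heat shock genes Hspa1b (-5.46 ± 0.10) and Hspa1a (-5.26 ± 0.21), Trp53inp2 (-5.36 ± 0.18), the phosphatase gene Dusp1 (-4.83 ± 0.09), Fosb (-4.80 ± 0.11) and Socs3 (-4.30 ± 0.25) had fallen the most. Cdkn1a (3.59 ± 0.14), Bcl2l11 (1.67 ± 0.11), Bcl2l1 (1.25 ± 0.17), Asns (1.25 ± 0.10), Ccnd2 (1.13 ± 0.06), Egr1 (1.09 ± 0.06), Myc (0.60 ± 0.12) and Cd86 (0.37 ± 0.07) rose. Zfx (-0.89 ± 0.09), Mcl1 (-0.90 ± 0.05) and Cd69 (-1.88 ± 0.09) fell. Atf4 (1.21 ± 0.06) rose and Ddit3 (-0.50 ± 0.09) fell on their brightest probe sets, but the mean of each gene's probe sets went the other way (-0.23 and 0.56). Xist (0.30 ± 0.20) was called only under median scaling (0.59). The call on Trib3 (1.61 ± 0.53) was lost without replicate 1 (1.58) or 2 (1.65) of cko at 0 h or replicate 1 (1.60) or 2 (1.63) at 12 h.

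Of 28 ribosome biogenesis genes, 25 rose and 1 fell in cko at 12 h, with Nop16 (3.30 ± 0.09) and Fbl (2.40 ± 0.06) as examples (list median 1.16 against -0.20 for all genes, adjusted p = 5.5e-10, and adjusted p = 0.017 with an estimated correlation). Of 19 sterol biosynthesis genes, 16 rose and 1 fell, Idi1 (3.49 ± 0.13) and Sqle (2.86 ± 0.13) in front (adjusted p = 5.8e-06, and adjusted p = 0.023 with an estimated correlation). Of 16 follicular identity genes, 14 fell and 0 rose, the complement receptor gene Cr2 (-4.17 ± 0.15) and Cd22 (-3.0 ± 0.05) in front (adjusted p = 1.7e-05, and adjusted p = 0.043 with an estimated correlation). All 11 MHC class II presentation genes fell, H2-Ob (-2.65 ± 0.12) and H2-DMb2 (-2.14 ± 0.06) among them (adjusted p = 2.2e-05, and adjusted p = 0.08 with an estimated correlation). Of 18 interferon response genes, 15 fell and 1 rose, Xaf1 (-2.99 ± 0.18) and Rtp4 (-2.87 ± 0.22) among the falls (adjusted p = 0.00056, and adjusted p = 0.079 with an estimated correlation). When adjusted over the list alone, 17 fell and 1 rose. Markers of other cells fell in the same contrast. Of 19 myeloid markers, 12 fell and 4 rose (list median -1.05, adjusted p = 0.032, and adjusted p = 0.21 with an estimated correlation), or 13 and 4 within the list alone. Of 14 T and NK cell markers, 8 fell and 0 rose (list median -0.68, adjusted p = 0.027, and adjusted p = 0.14 with an estimated correlation), also within the list alone. Both calls were lost with the filter at the 60th percentile (adjusted p = 0.066 and 0.055), and that on the T and NK markers without replicate 2 of cko at 12 h (adjusted p = 0.056). Of 33 integrated stress response genes, 20 rose and 5 fell, Ppp1r15a (-2.64 ± 0.14) among the falls and Mthfd2 (2.18 ± 0.09) and Ddit4 (1.91 ± 0.08) among the rises (adjusted p = 0.00056, and adjusted p = 0.089 with an estimated correlation). Oxidative phosphorylation genes gave 17 rises and 8 falls of 31, with Ndufa4 (3.46 ± 0.10) and Atp5o (3.22 ± 0.07) in front (adjusted p = 0.0014, and adjusted p = 0.15 with an estimated correlation). Here 7184 genes were called, 3152 higher and 4032 lower, 3401 of them at least 2-fold. The median of all genes was -0.20 and under median scaling 0.09, where 60.6% of the called genes were higher instead of 43.9%. The actin 5′ to 3′ ratio was 1.90 ± 0.13% at 0 h and 19.1 ± 0.07% at 12 h (SD, n = 2).

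**Figure D2:**
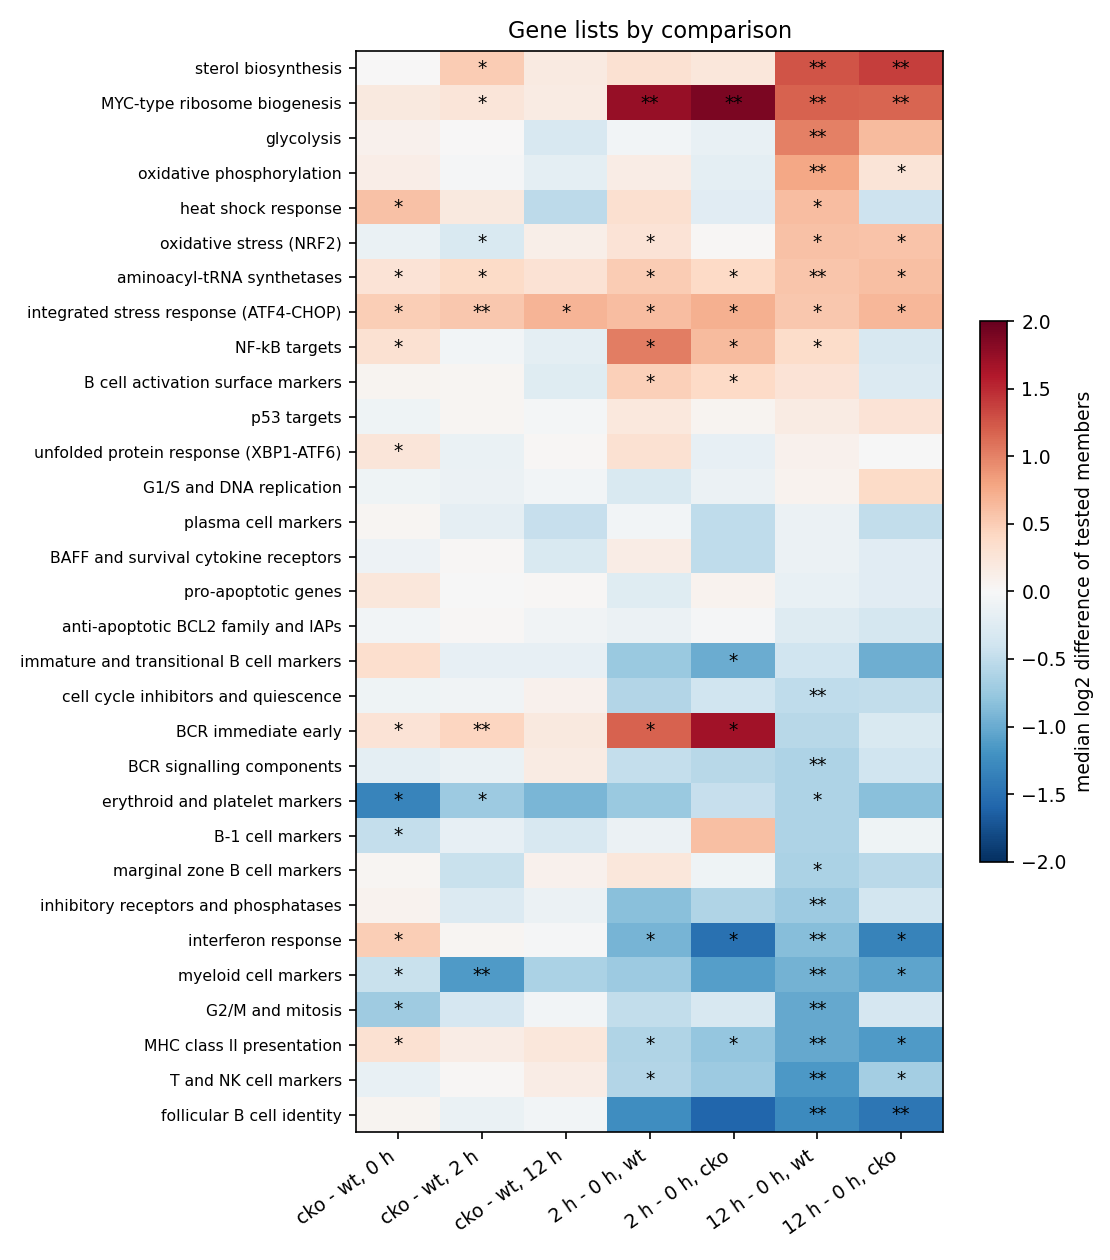
Median log2 change of each of the 31 tested gene lists (vertical axis) in 7 comparisons (horizontal axis), with calls that held with an estimated correlation marked by a double star and calls at the preset correlation alone by a single star. Ribosome biogenesis genes had medians of 1.74 and 1.18 in wild type at 2 and 12 h and 1.89 and 1.16 in cko.

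The responses of the genotypes were set against each other gene by gene. Over the 8828 genes called in either genotype at 2 h, the cko response followed the wild-type response with a slope of 0.959 and r = 0.883 across genes, and 5992 genes were called in the same direction against 141 in opposite directions. At 12 h, over 8541 genes, the slope was 0.730 and r was 0.572, with 3600 genes called in the same direction and 885 in opposite directions. Genes are not independent replicates, and no p is given. Both 2 h responses cross the control-probe division, while at 12 h only the cko response crosses it. How alike the responses are is thus confounded with the division, and the values at 2 h and 12 h cannot be set against each other.

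The genotypes were then compared at each time, which asks what differs on the arrays labelled cko, at rest and after receptor crosslinking. At 0 h the pseudokinase gene Trib3 (3.73 ± 0.53), a target of ATF4 and CHOP, had the largest difference with all arrays, with a signal of 36.5 ± 33.6 in wild type and 605 ± 23.0 in cko (SD, n = 2). Its wild-type signals were 60.2 and 12.7, and the difference was 4.43 without replicate 1 and 3.03 without replicate 2 of wild type. Akr1c13 (2.88 ± 0.36), the heat shock gene Hspa1a (2.50 ± 0.21), Cd1d2 (2.50 ± 0.25) and the glutathione-degrading enzyme gene Chac1 (2.42 ± 0.25) followed. The adenylate cyclase gene Adcy9 (-3.14 ± 0.33), the red cell anion exchanger gene Slc4a1 (-3.06 ± 0.20), Lrrc41 (-2.98 ± 0.17), Apol11b (-2.83 ± 0.40), Eid2 (-2.74 ± 0.33), Olfm4 (-2.66 ± 0.32), Cldn13 (-2.53 ± 0.34) and the neutrophil granule gene Lcn2 (-2.42 ± 0.11) were lower by the most. Without replicate 1 or 2 of cko, Adcy9 was -2.54 and -3.74 and Apol11b was -3.46 and -2.20. Asns (1.21 ± 0.10), Ddit3 (1.17 ± 0.09), Atf4 (0.60 ± 0.06), Myc (0.75 ± 0.12), Ccnd2 (0.37 ± 0.06), Xist (0.83 ± 0.20, signals of 33.7 in wild type and 72.0 in cko) and Zfx (1.23 ± 0.09) were higher in cko. So was Mcl1 (0.31 ± 0.05), whose call was lost under quantile normalization (0.03). Cd86 (-0.02 ± 0.07) and Bcl2l11 (-0.06 ± 0.11) were not called with all arrays, and Bcl2l11 was called without replicate 2 of cko (-0.28). Bcl2l1 (-0.60 ± 0.17), Cdkn1a (0.47 ± 0.14), Cd69 (0.36 ± 0.09) and Egr1 (0.21 ± 0.06) were called with all arrays but not without single arrays. Without replicate 2 of wild type or of cko, Bcl2l1 was -0.53 and -0.37 and Cd69 was 0.30 and 0.25. Cdkn1a was 0.32 without replicate 1 of wild type and 0.33 without replicate 1 of cko, and Egr1 was 0.14 without replicate 2 of wild type and 0.17 without replicate 1 of cko.

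Integrated stress response genes were higher in cko at 0 h. Of 33 tested, 18 were higher and 1 lower, and 20 were higher and 3 lower when adjusted over the list alone (list median 0.49, adjusted p = 1.7e-05, and adjusted p = 0.071 with an estimated correlation). Besides Trib3, Asns and Ddit3, the mitochondrial folate gene Mthfd2 (1.62 ± 0.09) and the serine synthesis gene Psat1 (0.96 ± 0.07) were among them. Of 14 heat shock genes, 10 were higher and 1 lower, Hspa1b (1.94 ± 0.10), Dnaja1 (1.29 ± 0.07) and Hsph1 (1.08 ± 0.06) in front (adjusted p = 0.00079, and adjusted p = 0.12 with an estimated correlation). Of 25 unfolded protein response genes, 12 were higher and 2 lower, with Xbp1 (0.93 ± 0.05) and Hsp90b1 (0.73 ± 0.09) as examples (adjusted p = 0.011, and adjusted p = 0.12 with an estimated correlation). Of 26 immediate early genes, 14 were higher and 2 lower, Jun (1.91 ± 0.10), Klf10 (1.64 ± 0.14) and Rgs2 (1.55 ± 0.08) among the former and Nr4a3 (-1.35 ± 0.10) among the latter (adjusted p = 0.0072, and adjusted p = 0.12 with an estimated correlation). Of 22 NF-kB targets, 12 were higher and 1 lower, with Nfkbie (0.78 ± 0.05) higher and Relb (-0.91 ± 0.10) lower (adjusted p = 0.0019, and adjusted p = 0.12 with an estimated correlation). Interferon response genes gave 8 higher and 1 lower of 18, Ifit1 (1.63 ± 0.26) and Rsad2 (-1.54 ± 0.20) at the ends (adjusted p = 0.0038, and adjusted p = 0.12 with an estimated correlation). Of 22 G2/M genes, 9 were lower and 2 higher, Ube2c (-1.86 ± 0.27) and Mki67 (-1.77 ± 0.39) among the former (adjusted p = 0.00079, and adjusted p = 0.071 with an estimated correlation), and this call was lost with the filter at the 60th percentile (adjusted p = 0.1), as was that on Mki67 with pseudocount 1 (-1.84). Adjusted over the list alone, 12 G2/M genes were lower, 4 immediate early genes and 2 NF-kB targets were lower, and the other counts were unchanged.

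Transcripts of other blood cells were lower on the cko arrays at 0 h. Of 19 myeloid markers, 8 were lower and 1 higher, and the calprotectin gene S100a9 (-2.04 ± 0.09) had a signal of 4034 ± 307 in wild type and 973 ± 101 in cko (SD, n = 2). S100a8 (-1.38 ± 0.09) and the antimicrobial peptide gene Camp (-1.32 ± 0.10) were lower as well (adjusted p = 0.00079 for the list, and adjusted p = 0.12 with an estimated correlation). Of 9 erythroid and platelet markers, 5 were lower and 0 higher, Car1 (-2.03 ± 0.34) and Car2 (-1.34 ± 0.18) among them (adjusted p = 0.00079, and adjusted p = 0.071 with an estimated correlation). Of 14 T and NK cell markers, 1 was higher and 1 lower (adjusted p = 0.58), and 0 were higher and 1 lower when adjusted over the list alone. Over all genes 3938 were called, 1983 higher and 1955 lower, and 684 differed at least 2-fold. The share of called genes that were higher was 50.4%, and 38.0% under median scaling. RNA quality differed between these groups by its control signs, with actin 5′ to 3′ ratios of 3.30 ± 0.04% in wild type and 1.90 ± 0.13% in cko (SD, n = 2) and Gapdh ratios of 2.52 and 1.56%.

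After 2 h of anti-IgM, Trib3 (3.54 ± 0.53) again had the largest difference, with signals of 128 ± 6.80 in wild type and 1660 ± 134 in cko (SD, n = 2). The G protein regulator genes Rgs13 (2.69 ± 0.24), Rgs2 (2.25 ± 0.08) and Rgs1 (2.17 ± 0.20), Chac1 (2.53 ± 0.25), the prostaglandin receptor gene Ptger2 (2.23 ± 0.30) and the amino acid transaminase gene Bcat1 (2.20 ± 0.19) were the next largest. Ptpmt1 (-2.97 ± 0.13), S100a9 (-2.77 ± 0.09), S100a8 (-2.77 ± 0.09), Lcn2 (-2.71 ± 0.11) the chitinase-like gene Chil3 (-2.65 ± 0.10) and Klhl22 (-2.56 ± 0.12) were lower by the most. Asns (1.41 ± 0.10), Ddit3 (1.0 ± 0.09), Atf4 (0.70 ± 0.06), Egr1 (0.68 ± 0.06) and Cd69 (0.53 ± 0.09) were higher in cko and Bcl2l11 (-0.58 ± 0.11) was lower. The mean of the probe sets of Ddit3 was not called (0.48). Xist (0.21 ± 0.20), Mcl1 (0.05 ± 0.05), Ccnd2 (-0.16 ± 0.06) and Cdkn1a (-0.37 ± 0.14) were not called, but Mcl1 was with the mean of its probe sets (0.25), Ccnd2 under quantile normalization (-0.17) and Cdkn1a with pseudocount 64 (-0.35). Myc (0.31 ± 0.12) and Bcl2l1 (-0.46 ± 0.17) were not called with all arrays (adjusted p = 0.069 and 0.064), but both were without replicate 1 or 2 of cko at 0 h. So was Bcl2l1 without replicate 1 or 2 of cko at 12 h, with values of 0.31 and -0.46 that did not move. The call on Cd86 (-0.21 ± 0.07) was lost without replicate 1 (-0.21) or 2 (-0.21) of wild type or replicate 1 of cko (-0.14).

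Integrated stress response genes were again higher in cko. Of 33 tested, 18 were higher and 1 lower, Eif4ebp1 (1.45 ± 0.07) and Psat1 (1.02 ± 0.07) next to Asns (list median 0.54, adjusted p = 7.5e-08, and adjusted p = 0.039 with an estimated correlation). With p adjusted over the list alone, 19 were higher. Of 26 immediate early genes, 17 were higher and 2 lower, Btg2 (0.68 ± 0.07) next to Rgs2, Rgs1 and Egr1 (adjusted p = 3.2e-07, and adjusted p = 0.039 with an estimated correlation). Adjusted over the list alone, 21 were higher. Of 19 aminoacyl-tRNA synthetase genes, 11 were higher and 2 lower, Tars (0.71 ± 0.07) and Mars1 (0.68 ± 0.08) among the former (adjusted p = 0.00064, and adjusted p = 0.061 with an estimated correlation). Ribosome biogenesis genes gave 11 higher and 1 lower of 28, with Dkc1 (0.67 ± 0.13) and Bop1 (0.52 ± 0.10) as examples (adjusted p = 0.0019, and adjusted p = 0.061 with an estimated correlation). When adjusted over the list alone, 13 higher. Of 19 sterol biosynthesis genes, 10 were higher and 2 lower, Hsd17b7 (0.84 ± 0.12) and Insig1 (0.67 ± 0.11) among the former (adjusted p = 0.0019, and adjusted p = 0.061 with an estimated correlation). With p adjusted over the list alone, 11 were higher and 3 lower.

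Myeloid markers were lower on the cko arrays at 2 h, 12 of 19 with 1 higher, and 13 lower when adjusted over the list alone (list median -1.14, adjusted p = 8.7e-08, and adjusted p = 0.045 with an estimated correlation). The granule genes Ngp (-2.49 ± 0.09) and Camp (-2.41 ± 0.10) and the lysozyme gene Lyz1 (-1.81 ± 0.06) were among them. In total 3469 genes were called, 1560 higher and 1909 lower, and 508 differed at least 2-fold. The actin 5′ to 3′ ratio was 8.46 ± 0.07% in wild type and 10.7 ± 0.14% in cko (SD, n = 2).

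**Figure D3:**
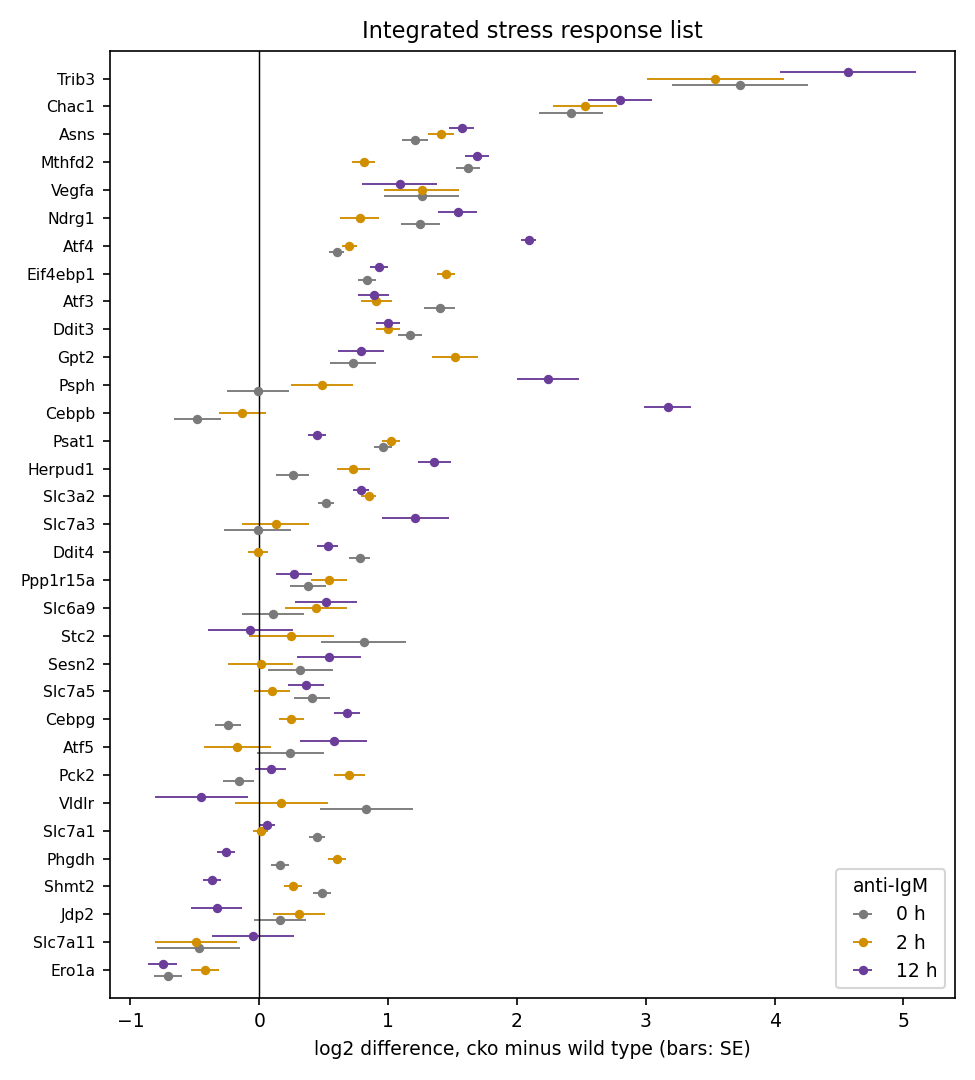
Log2 difference between cko and wild type ± SE (horizontal axis) of the 33 tested integrated stress response genes (vertical axis) at 0, 2 and 12 h, n = 2 arrays per group. The list medians were 0.49 at 0 h, 0.54 at 2 h and 0.68 at 12 h.

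At 12 h genotype is confounded with the control-probe division. Trib3 (4.57 ± 0.53) differed most with all arrays. Its signals were 90.0 ± 98.7 in wild type and 1884 ± 23.5 in cko (SD, n = 2). The wild-type signals were 20.2 and 159.8, and the difference was 3.43 and 5.71 without replicate 1 or 2 of wild type. It was followed by Uqcrh (4.04 ± 0.12), the ribosomal protein gene Rpl22l1 (3.76 ± 0.12), Nop58 (3.52 ± 0.13), Ndufs4 (3.51 ± 0.11), the cytokine gene Il6 (3.39 ± 0.33), Thoc2 (3.28 ± 0.07) and the stress response transcription factor gene Cebpb (3.17 ± 0.18). Mid1 (-3.63 ± 0.14), Hspa1a (-3.35 ± 0.21), the DNA repair gene Ercc2 (-3.11 ± 0.32) and Dis3l (-3.10 ± 0.32) were lower by the most. Bcl2l1 (-1.39 ± 0.17) was lower in cko, with signals of 1977 ± 283 in wild type and 751 ± 174 in cko (SD, n = 2). Atf4 (2.09 ± 0.06), Asns (1.57 ± 0.10), Ddit3 (1.0 ± 0.09), Myc (1.27 ± 0.12), Cd69 (0.85 ± 0.09), Egr1 (0.47 ± 0.06) and Zfx (0.38 ± 0.09) were higher, though 1 of the 2 probe sets of Atf4 was called in the opposite direction. Mcl1 (-0.38 ± 0.05) and Cd86 (-0.28 ± 0.07) are given as values, since their calls were lost under median scaling (-0.16 and -0.06) and the mean of the probe sets of Cd86 went the other way (0.20). Bcl2l11 (0.07 ± 0.11), Xist (-0.18 ± 0.20), Ccnd2 (-0.13 ± 0.06) and Cdkn1a (-0.07 ± 0.14) were not called, and the means of the probe sets of Ccnd2 and Cdkn1a were above 0 (0.25 and 1.25). Bcl2l11 was called under quantile normalization (0.35) and median scaling (0.29).

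Of 33 integrated stress response genes, 20 were higher in cko at 12 h and 3 lower, Mthfd2 (1.69 ± 0.09) among the former, with the same counts when adjusted over the list alone (list median 0.68 against -0.17 for all genes, adjusted p = 7.3e-06, and adjusted p = 0.15 with an estimated correlation). It was the only list called at the preset correlation. Of 14 heat shock genes, 3 were higher and 8 lower, Hspa1a and Hspa1b (-2.62 ± 0.10) among the latter (adjusted p = 0.38). Myeloid markers gave 3 higher and 10 lower of 19, S100a8 (-2.28 ± 0.09) among the latter (adjusted p = 0.26), and 4 higher and 11 lower when adjusted over the list alone. Of 22 NF-kB targets, 2 were higher and 10 lower, Nfkb2 (-1.65 ± 0.11) and Nfkbie (-1.41 ± 0.05) among the latter (adjusted p = 0.38), with a list median of -0.20 that was 0.02 under median scaling.

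At 12 h 6258 genes were called, 2612 higher and 3646 lower, and 2189 differed at least 2-fold. The median of all genes was -0.17 and under median scaling 0.04, where 58.0% of the called genes were higher instead of 41.7%. The actin 5′ to 3′ ratio was 2.19 ± 0.11% in wild type and 19.1 ± 0.07% in cko (SD, n = 2). Genes called at 12 h overlapped with those called at 2 h, 825 higher at both times (334 if independent) and 1226 lower at both (571 if independent), against 471 in opposite directions (876 if independent, r = 0.37 across genes). Between 0 h and 12 h, 619 were higher at both times (425 if independent) and 909 lower at both (585 if independent), while 1159 went in opposite directions (1012 if independent, r = 0.13). Between 0 h and 2 h these were 568 (254), 780 (306) and 412 (561), with r = 0.34.

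**Figure D4:**
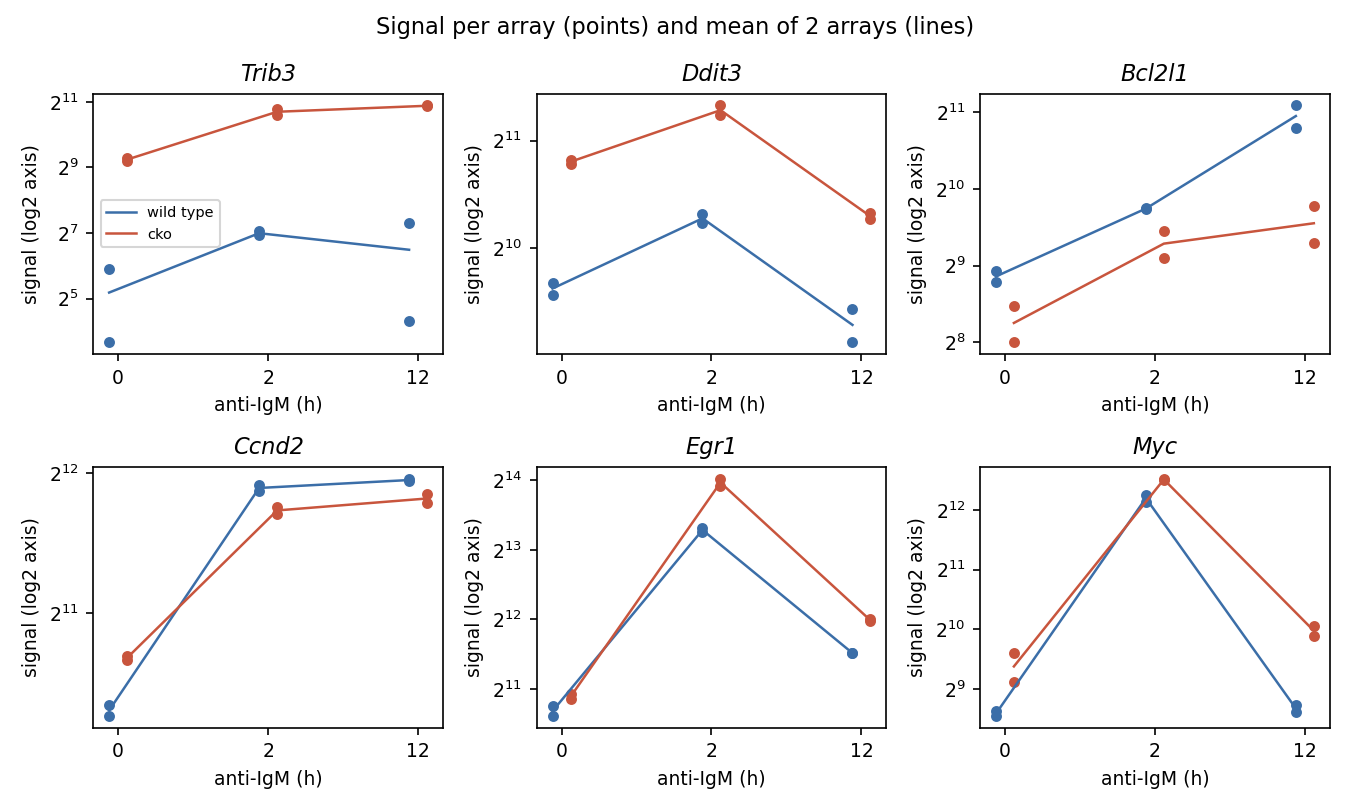
Signal (vertical axis, logarithmic) of Trib3, Ddit3, Bcl2l1, Ccnd2, Egr1 and Myc at 0, 2 and 12 h of anti-IgM (horizontal axis), with 1 point per array and lines through the means of the 2 arrays of each group. Trib3 means lay at 36.5, 128 and 90.0 in wild type and at 605, 1660 and 1884 in cko.

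Averaged over the 3 times, with n = 6 arrays per genotype, Trib3 (3.95 ± 0.31), Chac1 (2.58 ± 0.14), Bcat1 (2.01 ± 0.11), Rgs13 (1.76 ± 0.14), the pattern receptor gene Tlr1 (1.71 ± 0.12) and Cd1d2 (1.70 ± 0.15) were higher in cko by the most. Slc4a1 (-2.53 ± 0.11), Cep170b (-2.50 ± 0.10), the mitochondrial phosphatase gene Ptpmt1 (-2.44 ± 0.08), Dis3l (-2.31 ± 0.18), Klhl22 (-2.25 ± 0.07) and Lcn2 (-2.22 ± 0.06) were lower by the most. Asns (1.40 ± 0.06), Atf4 (1.13 ± 0.03), Ddit3 (1.06 ± 0.05), Myc (0.78 ± 0.07), Cd69 (0.58 ± 0.05), Egr1 (0.45 ± 0.04) and Zfx (0.64 ± 0.05) were higher. Bcl2l1 (-0.81 ± 0.10) was lower, as was Cd86 (-0.17 ± 0.04) on its brightest probe set but not on the mean of its probe sets (-0.01). The call on Bcl2l11 (-0.19 ± 0.06) was lost without replicate 2 of wild type at 0 h (-0.16), 2 h (-0.19) or 12 h (-0.17) and without replicate 2 of cko at 2 h (-0.17) or 12 h (-0.17). Xist (0.28 ± 0.12), Ccnd2 (0.03 ± 0.03), Cdkn1a (0.01 ± 0.08) and Mcl1 (-0.01 ± 0.03) were not called, and the means of the probe sets of Ccnd2 and Cdkn1a were called (0.28 and 0.69), as was that of Mcl1 (0.11), and Xist was called under median scaling (0.33). With the duplicate arrays averaged, the 12 genes of the largest differences and Asns were still called, and Atf4, Ddit3, Myc, Cd69, Egr1, Zfx, Bcl2l1 and Cd86 were not.

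Of 33 integrated stress response genes, 25 were higher over the 3 times and 1 was lower, Mthfd2 (1.37 ± 0.05) among the former (list median 0.44, adjusted p = 6.9e-10, and adjusted p = 0.041 with an estimated correlation). Adjusted over the list alone, 26 were higher. Of 19 aminoacyl-tRNA synthetase genes, 14 were higher and 4 lower, Cars (1.40 ± 0.13) and Tars (0.92 ± 0.04) in front (adjusted p = 0.0023, and adjusted p = 0.1 with an estimated correlation). Of 26 immediate early genes, 16 were higher and 3 lower, Rgs1 (1.59 ± 0.12), Rgs2 (1.53 ± 0.04) and Btg2 (1.06 ± 0.04) among the former (adjusted p = 0.00042, and adjusted p = 0.1 with an estimated correlation). When adjusted over the list alone, 17 were higher. Myeloid markers gave 13 lower and 0 higher of 19, S100a8 (-2.14 ± 0.05) and S100a9 (-2.03 ± 0.05) in front (adjusted p = 9e-05, and adjusted p = 0.1 with an estimated correlation). Of 9 erythroid and platelet markers, 6 were lower and 0 higher, Alas2 (-1.64 ± 0.10) next to Slc4a1 (adjusted p = 0.0023, and adjusted p = 0.1 with an estimated correlation). In all, 5831 genes were called, 2593 higher and 3238 lower, and 373 differed at least 2-fold. The share higher was 44.5%, against 52.2% under median scaling and 15.4% of the genes called with duplicates averaged. With the duplicate arrays averaged, which leaves 2 residual degrees of freedom and takes the error from the spread over the times, 91 genes were called, Tars and Btg2 not among them, and without the 12 h arrays 4476 were.

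Across the separate comparisons, which share no arrays, 304 genes were higher in cko at all 3 times (54 if independent) and 534 were lower (92 if independent). At least 2-fold at all 3 times, 15 were higher and 72 were lower. The higher ones, singled out after their values were seen, included Trib3, Chac1, Asns, Ddit3, Vegfa and Cars of the stress response and synthetase lists, and also Bcat1, Tlr1, Pdcd1lg2, Il15ra, Rgs1, Rgs13, Cd1d2 and Crisp3.

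The interaction of genotype and time was tested, each value being the cko response to anti-IgM minus the wild-type response. At 2 h the kinase gene Map3k12 (3.02 ± 0.38), the splicing regulator gene Esrp2 (2.94 ± 0.32) and the lectin receptor gene Cd302 (2.90 ± 0.33) had the largest differences upward. Akr1c13 (-3.56 ± 0.51), the B cell receptor chain gene Cd79a (-2.84 ± 0.16) and the purine synthesis gene Atic (-2.68 ± 0.12) had the largest downward. The signal of Cd79a was 1188 ± 248 and 1391 ± 162 in wild type at 0 and 2 h, and 2411 ± 27.9 and 383.5 ± 7.81 in cko (SD, n = 2). Whether Cd79a itself was modified in the mice is not given. The difference was upward for Egr1 (0.47 ± 0.09) and downward for Ccnd2 (-0.53 ± 0.08), Cdkn1a (-0.84 ± 0.20) and Zfx (-0.91 ± 0.13). The calls on Cdkn1a and Zfx were lost with the mean of their probe sets (-0.57 and -0.21). Asns (0.21 ± 0.14), Cd69 (0.17 ± 0.12), Bcl2l1 (0.14 ± 0.24), Atf4 (0.10 ± 0.08), Ddit3 (-0.17 ± 0.13), Trib3 (-0.19 ± 0.75), Cd86 (-0.19 ± 0.10) and Xist (-0.62 ± 0.29) were not called, though the mean of the probe sets of Asns was (0.64). Nor was Myc (-0.43 ± 0.17) with all arrays, though it was without replicate 1 of cko at 0 h (-0.67). The calls on Bcl2l11 (-0.52 ± 0.15) and Mcl1 (-0.26 ± 0.07) were lost without single arrays. For Bcl2l11 these were replicate 1 of wild type at 0 h (-0.45), replicates 1 (-0.52) and 2 (-0.52) of wild type at 2 h, replicate 2 of cko at 0 h (-0.30) and replicates 1 (-0.56) and 2 (-0.48) of cko at 2 h. For Mcl1 they were replicate 1 of wild type at 0 h (-0.25) or 2 h (-0.23) and replicate 2 of cko at 0 h (-0.22). Mcl1 turned to 0.02 under quantile normalization and 0.03 with the mean of its probe sets, and Bcl2l11 lost its call under median scaling (-0.43) and with the mean of its probe sets (-0.22). There were 2491 genes called, 1047 with an upward and 1444 with a downward difference, 599 of them at least 2-fold, and 1594 with the mean of each gene's probe sets. The upward share was 42.0%, and 56.4% under median scaling. Probe sets of the same gene, both called and at least 2-fold, went opposite ways in 12.7% of 71 pairs.

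Of 22 NF-kB targets, 11 had a downward and 1 an upward difference in the 2 h response (adjusted p = 0.0023). The inhibitor genes Bcl3 (-1.25 ± 0.13), Tnfaip3 (-0.99 ± 0.11) and Nfkbie (-0.96 ± 0.08) were among the former. Over the list alone, 15 were downward. Of 25 unfolded protein response genes, 10 were downward and 0 upward (adjusted p = 0.0093). Xbp1 (-1.03 ± 0.08) and Hsp90b1 (-0.89 ± 0.12) were in front. Over the list alone, 1 was upward. For cko against wild type, these lists' medians were 0.31 and 0.24 at 0 h and, uncalled, -0.06 and -0.13 at 2 h. Of 19 myeloid markers, 8 were downward and 0 upward, Csf1r (-1.68 ± 0.16) and Lyz1 (-1.62 ± 0.09) among them (adjusted p = 0.0037). Adjusted p was 0.32 for all 3 with an estimated correlation. The integrated stress response list was not called, with 6 genes upward and 3 downward of 33 (adjusted p = 0.51).

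At 12 h the fatty acid elongation gene Hacd1 (4.32 ± 0.41), Uqcrh (3.99 ± 0.17) and Thoc2 (3.66 ± 0.10) had the largest differences in response upward. Hspa1a (-5.85 ± 0.30), Hspa1b (-4.56 ± 0.14) and Zfp516 (-3.79 ± 0.37) had the largest downward. The difference was upward for Cd69 (0.49 ± 0.12), which fell in both genotypes. That in Zfx (-0.85 ± 0.13) was downward, and its call was lost with the mean of its probe sets (-0.43). Atf4 (1.49 ± 0.08), Ccnd2 (-0.50 ± 0.08) and Mcl1 (-0.68 ± 0.07) are given as values, since their calls were lost with the mean of the probe sets of Atf4 (0.10), with median scaling for Ccnd2 (-0.21) or with quantile normalization for Mcl1 (-0.12). Cd86 (-0.26 ± 0.10) was not called with all arrays and was called without replicate 1 of cko at 0 h (-0.31) and under quantile normalization (-0.32). Trib3 (0.84 ± 0.75), Bcl2l11 (0.13 ± 0.15) and Ddit3 (-0.17 ± 0.13) were not called with all arrays, but they were without replicate 2 of wild type at 12 h (1.98), replicate 2 of cko at 0 h (0.36) and replicate 1 of wild type at 12 h (-0.32), in that order. Bcl2l11 was also called under quantile normalization (0.47) and median scaling (0.42), and Trib3 with the mean of its probe sets (0.91). The difference in Xist (-1.01 ± 0.29) was not called under median scaling (-0.72) or without replicate 2 of cko at 12 h (-0.89). That in Bcl2l1 (-0.79 ± 0.24) was not called without replicate 1 of wild type at 0 h (-0.72) or 12 h (-0.65) or replicate 1 of cko at 0 h (-0.57) or 12 h (-0.56). Myc (0.52 ± 0.17), Asns (0.36 ± 0.14), Egr1 (0.26 ± 0.09) and Cdkn1a (-0.53 ± 0.20) were called with all arrays at adjusted p of 0.025, 0.046, 0.025 and 0.046 and each lost its call without single arrays of the groups compared. Among these Myc was 0.48 without replicate 1 of wild type at 0 h, 0.46 without replicate 1 at 12 h, 0.28 without replicate 1 of cko at 0 h and 0.44 without replicate 2 at 12 h. Egr1 was 0.19 without replicate 1 of wild type at 0 h, 0.27 and 0.26 without replicate 1 or 2 at 12 h, 0.22 without replicate 2 of cko at 0 h and 0.25 without replicate 2 at 12 h. Cdkn1a was -0.38 without replicate 1 of wild type at 0 h, -0.58 and -0.48 without replicate 1 or 2 at 12 h, -0.39 without replicate 1 of cko at 0 h and -0.41 without replicate 2 at 12 h, and the mean of its probe sets went the other way (0.54). Asns lost its call without replicate 2 of wild type at 0 h (0.25), replicate 1 or 2 at 2 h (0.36 and 0.36) or replicate 1 at 12 h (0.28). It was also lost without replicate 1 or 2 of cko at 0 h (0.40 and 0.32), 2 h (0.36 and 0.36) or 12 h (0.31 and 0.41).

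There were 5267 genes called in the interaction at 12 h, 2290 with an upward and 2977 with a downward difference, and 2527 of them at least 2-fold. This contrast is confounded with the control-probe division, and probe sets of the same gene, both called and at least 2-fold, went opposite ways in 31.9% of 1105 pairs. The median of all genes was -0.17 and under median scaling 0.12, where 64.9% of the called differences were upward instead of 43.5%. Of 22 NF-kB targets, 13 had a downward and 2 an upward difference in the 12 h response, Nfkbie (-2.19 ± 0.08) and Nfkb2 (-2.01 ± 0.15) among the former (list median -0.71, adjusted p = 0.029, and adjusted p = 0.38 with an estimated correlation). When adjusted over the list alone, 15 were downward and 3 upward. This call was lost under median scaling (adjusted p = 0.079), with the filter at the 60th percentile (adjusted p = 0.087) and without replicate 1 of wild type at 0 h (adjusted p = 0.051).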

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

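The tests below on the number of genes at 12 h, on the integrated stress response and on the control-probe division as a source of the neutrophil signal were chosen only after the result was seen, whereas the neutrophil list was written before. Each pattern was noticed and tested on the same arrays.

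The 2 h response to anti-IgM differed between the genotypes in a direct test of that difference for 2491 genes, and for 1594 with the mean of each gene's probe sets. The upward share was 42.0%, but 56.4% under median scaling. Probe sets of the same gene, both called and at least 2-fold, went opposite ways in 12.7% of 71 pairs (95% Wilson interval 6.81 to 22.4). The actin 5′ to 3′ ratio went from 3.30 to 8.46% in wild type and from 1.90 to 10.7% in cko. The value is the cko response minus the wild-type response. Among the genes named, it was above 0 for Map3k12 (3.02 ± 0.38), Esrp2 (2.94 ± 0.32), Cd302 (2.90 ± 0.33) and Egr1 (0.47 ± 0.09). It was below 0 for Akr1c13 (-3.56 ± 0.51), Cd79a (-2.84 ± 0.16), Atic (-2.68 ± 0.12), Zfx (-0.91 ± 0.13), Cdkn1a (-0.84 ± 0.20), Ccnd2 (-0.53 ± 0.08), Bcl3 (-1.25 ± 0.13), Tnfaip3 (-0.99 ± 0.11), Nfkbie (-0.96 ± 0.08), Xbp1 (-1.03 ± 0.08), Hsp90b1 (-0.89 ± 0.12), Csf1r (-1.68 ± 0.16) and Lyz1 (-1.62 ± 0.09). The calls on Zfx and Cdkn1a were lost with the mean of their probe sets (-0.21 and -0.57). Bcl2l11 (-0.52 ± 0.15) and Mcl1 (-0.26 ± 0.07) had adjusted p of 0.028 and 0.015. Bcl2l11 was not called without replicate 1 of wild type at 0 h (-0.45), replicate 1 or 2 at 2 h (-0.52 and -0.52), replicate 2 of cko at 0 h (-0.30) or replicate 1 or 2 at 2 h (-0.56 and -0.48). Mcl1 was not called without replicate 1 of wild type at 0 h (-0.25) or 2 h (-0.23) or replicate 2 of cko at 0 h (-0.22), and it turned to 0.02 under quantile normalization and 0.03 with the mean of its probe sets. Bcl2l11 was also not called under median scaling (-0.43) or with the mean of its probe sets (-0.22). The lists of NF-kB targets, myeloid markers and unfolded protein response genes moved downward in the same test (adjusted p = 0.0023, 0.0037 and 0.0093, and for each adjusted p = 0.32 with an estimated correlation). Heat shock genes had an adjusted p of 0.04, and adjusted p = 0.34 with an estimated correlation. It was 0.11 without replicate 1 of wild type at 0 h, 0.055 without replicate 1 at 2 h, 0.059 and 0.059 without replicate 1 or 2 at 12 h and 0.071 without replicate 2 of cko at 0 h.

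At 12 h the responses differed between the genotypes for 5267 genes in the same direct test, which is confounded with the control-probe division. Probe sets of the same gene, both called and at least 2-fold, went opposite ways in 31.9% of 1105 pairs. The difference was upward for Hacd1 (4.32 ± 0.41), Uqcrh (3.99 ± 0.17), Thoc2 (3.66 ± 0.10) and Cd69 (0.49 ± 0.12), and downward for Hspa1a (-5.85 ± 0.30), Hspa1b (-4.56 ± 0.14), Zfp516 (-3.79 ± 0.37), Nfkbie (-2.19 ± 0.08) and Nfkb2 (-2.01 ± 0.15). Zfx (-0.85 ± 0.13), Atf4 (1.49 ± 0.08), Mcl1 (-0.68 ± 0.07) and Ccnd2 (-0.50 ± 0.08) are given as values. The calls on Zfx and Atf4 were lost with the mean of their probe sets (-0.43 and 0.10), that on Mcl1 with quantile normalization (-0.12) and that on Ccnd2 with median scaling (-0.21). Xist (-1.01 ± 0.29) was not called without replicate 2 of cko at 12 h (-0.89). Bcl2l1 (-0.79 ± 0.24), Cdkn1a (-0.53 ± 0.20), Myc (0.52 ± 0.17), Egr1 (0.26 ± 0.09) and Asns (0.36 ± 0.14) had adjusted p of 0.018, 0.046, 0.025, 0.025 and 0.046, and the report gives their values without each array that changes the call. Lists of G2/M, heat shock and NF-kB target genes each had an adjusted p of 0.029, with medians of 0.83, -0.64 and -0.71, and adjusted p = 0.38 with an estimated correlation. Under median scaling these were 0.079, 0.058 and 0.079, and with the filter at the 60th percentile 0.72, 0.087 and 0.087. Without replicate 1 of wild type at 0 h these were 0.051, 0.096 and 0.051. G2/M genes were not called without replicate 2 of wild type at 0 h (0.053) or replicate 1 of cko at 12 h (0.057), nor were heat shock genes without replicate 1 of wild type at 12 h (0.055).

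Control probe sets, which the comparisons do not use, gave 5′ signals relative to 3′ signals above those of the wild-type 0 h arrays in 3 groups. For actin the means were 8.46% in wild type at 2 h, 10.7% in cko at 2 h and 19.05% in cko at 12 h, against 3.30% in wild type at 0 h. For Gapdh they were 5.775, 8.385 and 12.8% in the same groups, against 2.52%.

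More genes differed between the genotypes at 12 h (6258) than at 0 h (3938) or 2 h (3469), and the control-probe division runs between the genotypes at 12 h alone. Where it does, probe sets of the same gene that were both called and at least 2-fold changed went opposite ways in 22.5% of 813 pairs (95% Wilson interval 19.8 to 25.5), against 9.8% of 102 pairs at 0 h (5.41 to 17.1), 0 of 93 at 2 h (up to 3.97) and 4.2% of 1000 in the wild-type 12 h response (3.12 to 5.63). Also across the division, the cko 12 h response gave 18.4% and the 12 h interaction 31.9%, but the 2 h responses gave 10.8% in wild type and 12.1% in cko, inside the interval at 0 h, so the pairs leave open whether arrays prepared apart account for part of the 12 h differences. A 2 h state lasting to 12 h was tested by the share of the way from wild-type 12 h to the 2 h level. Immediate early genes lay 0.22 of that way (19 genes, bootstrap interval -0.01 to 0.35) and all genes 0.53. The interval argues against immediate early genes staying at their 2 h level. It does not exclude a lasting state of other genes. The cko 12 h and both 2 h groups lie on the same side of the division, so the share of all genes may carry it. A biological difference between the genotypes at 12 h stays open and is confounded with the division.

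Integrated stress response genes were higher in cko at 0 h and 2 h, where both genotypes lie on 1 side of the division, with list medians of 0.49 and 0.54. This argues against the division as the source, which would leave both medians near 0, while the smaller was 0.49. Fewer cells of other types in the cko samples would raise B cell genes by about as much. At 2 h this was argued against as the whole cause, since the medians of the follicular, MHC class II and sort gate lists were -0.13 (bootstrap interval -0.48 to 0.09), 0.15 (0.06 to 0.25) and -0.05 (-0.27 to 0.11), while at 0 h they were 0.06 (-0.12 to 0.30), 0.30 (0.09 to 0.40) and, for the 4 sort gate genes, 0.58 (0.20 to 1.0), so the former pair goes against it there and the last leaves it open. A biological effect of the genotype stays open as a hypothesis, as do other differences between the samples, such as handling or RNA quality, which were not tested. With an estimated correlation the list call held at 2 h (adjusted p = 0.039) and not at 0 h (0.071) or 12 h (0.15).

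Myeloid markers were lower in cko at 0 h and 2 h. The control-probe division was argued against as the source, because the weaker of the list medians at those times was -0.45. Fewer carried-over neutrophils are a candidate explanation. Of 18 neutrophil genes listed apart, 14 were tested. In 12 (85.7%) values were below 0 at both times, called or not. At 0 h 9 were called lower, at 2 h 8, and 0 higher. None of the genes is on a list described in the report. The highest signals among them were those of Hp (724.5 in wild type and 190.2 in cko at 0 h), Pglyrp1 (556.0 and 258.3), Wfdc21 (545.1 and 195.5) and Ifitm6 (518.9 and 87.3), and the sort gate on B220 and CD23 would remove such cells. A difference in these genes within the B cells was not tested.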

How the results depend on the processing

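The term for the control-probe division, the mean of duplicate arrays and the mean without 12 h were chosen only after the result was seen. Of the counts of called genes, 10 of 10 stayed within 1.5 times their main value under quantile normalization, median scaling, both pseudocounts, both other filters, no trend, array weights, every probe set and the replicate block, as did 7 of 7 with only the groups compared. The share of called genes that were higher passed 50% with every probe set between the genotypes at 12 h (54.5%) and in the mean (53%), in the cko 12 h response (53.5%) and in the 12 h interaction (56.5%). With the mean of a gene's probe sets it did so between the genotypes at 2 h (50.7%) and in the mean (50.6%) and in the 12 h interaction (50.4%). The directions of the 83 list calls reversed in 0 cases under the alternatives run for lists. Only the groups compared, the 2-fold minimum, averaged duplicates and the division as a term were not run for lists, and the mean without 12 h covers 5 of the calls. Of these calls, 60 were lost with an estimated correlation, 23 at the 60th percentile, 11 with quantile normalization, 10 with pseudocount 1, 7 with every probe set, 6 with the replicate block, 5 with the mean of a gene's probe sets, 4 with median scaling, 4 without a filter, 2 with pseudocount 64 and 52 when an array was left out (944 held), and 0 with fry or array weights. Camera does not use the intensity trend, so the lists were not run without it. A minimum of 2-fold, which by construction keeps fewer genes, gave 684 genes at 0 h, 508 at 2 h, 2189 at 12 h and 373 in the mean for cko against wild type. It gave 3724 and 2068 for the wild-type responses at 2 and 12 h, 4274 and 3401 for the cko responses, and 599 and 2527 for the interactions. With the mean of a gene's probe sets 1594 genes were called in the 2 h interaction, and the cause was not tested. The integrated stress response call was lost with an estimated correlation at 0 h (adjusted p = 0.071) and 12 h (adjusted p = 0.15), where the estimated correlation was 0.027 against the preset 0.01. The size of the correlation alone does not account for such losses. At 0 h the calls on erythroid and platelet markers and on G2/M genes were lost too (both adjusted p = 0.071). Their estimated correlations were -0.067 and -0.01. With duplicates averaged 91 genes were called in the mean genotype difference, and 4476 without 12 h. Averaging leaves 2 residual degrees of freedom and takes the error from the spread over the times, and these causes were not separated. With the control-probe division as a term 4708 genes were called for the 2 h responses and 5090 for the 12 h responses, where 1 time effect is fitted for both genotypes, and the cause was not tested.

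Without 1 array, the counts ran from 2876 to 3942 at 0 h, 2366 to 3510 at 2 h, 5360 to 6317 at 12 h and 5429 to 5624 in the mean for cko against wild type. They ran from 6460 to 7309 and 5092 to 5908 for the wild-type responses, 6975 to 7727 and 6298 to 7223 for the cko responses, and 1837 to 2506 and 4564 to 5219 for the interactions. The adjusted p of the integrated stress response list ran from 1.3e-06 to 0.00027 at 0 h, 8.6e-09 to 8.7e-07 at 2 h, 1.8e-06 to 2.3e-05 at 12 h and 3e-10 to 3.1e-09 in the mean.

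Directions reversed for named genes as follows. With the mean of a gene's probe sets, Cdkn1a was 1.25, Ccnd2 0.25 and Cd86 0.20 between the genotypes at 12 h, Mcl1 was 0.11 in the mean, Atf4 was -0.23 and Ddit3 0.56 in the cko 12 h response, and in the interactions Mcl1 was 0.03 at 2 h and Cdkn1a 0.54 at 12 h. With quantile normalization Mcl1 was 0.02 in the 2 h interaction. For the probe-set means the construction shows the cause, which is that other probe sets of these genes went the other way, and for quantile normalization the cause was not tested. Of the 367 named pairs of a gene and a contrast, 332 passed the threshold, 302 stayed on their side of it and 359 kept their direction under the alternatives run for single genes, each array left out included. Every probe set, only the groups compared, the 2-fold minimum and the 3 later additions were not run for them.

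Median scaling moved the median of all genes from -0.24 to -0.04 in the wild-type 2 h response, from -0.32 to -0.03 in cko at 2 h, from -0.20 to 0.09 in cko at 12 h, from -0.17 to 0.04 between the genotypes at 12 h and from -0.17 to 0.12 in the 12 h interaction. Signals near the floor limit what can be tested, and probe sets under the 40th percentile were not.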

Other observations

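Of the tests in this part, the reading of the neighbouring genes and the test of the chromosome of Zfx were chosen only after the result was seen, and the other tests were written before.

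Components of B cell receptor signalling fell in wild type at 12 h, 14 of 23 with 5 higher, with the same counts adjusted over the list alone. Syk (-1.56 ± 0.07), the kinase next to the receptor, Rasgrp3 (-1.34 ± 0.07), Prkcb (-1.29 ± 0.06) and Cd79b (-1.06 ± 0.05) were among the falls (list median -0.61, adjusted p = 0.001, and adjusted p = 0.03 with an estimated correlation). Genes of MHC class II presentation fell as early as 2 h. In wild type 10 of 11 fell, H2-DMa (-2.06 ± 0.06) and H2-DMb2 (-1.63 ± 0.06) in front (list median -0.60 against -0.24 for all genes, adjusted p = 0.009, and adjusted p = 0.18 with an estimated correlation), and in cko all 11 fell, H2-Oa (-1.91 ± 0.08) and H2-DMb2 (-1.89 ± 0.06) in front (list median -0.77 against -0.32, adjusted p = 0.0053, and adjusted p = 0.23 with an estimated correlation). Both calls were lost under quantile normalization (adjusted p = 0.061 and 0.15). T and NK cell markers fell too in wild type at 2 h, 9 of 14 with 0 higher (list median -0.58, adjusted p = 0.043, and adjusted p = 0.18 with an estimated correlation). That call was lost under quantile normalization (adjusted p = 0.055), without replicate 1 of wild type at 0 h (0.059) and without replicate 1 or 2 of cko at 2 h (0.052 and 0.052).

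Of the genes of the sort gate, the complement receptor gene Cr2 (1.0 ± 0.15) was higher in cko at 0 h. Cd93 (0.85 ± 0.42), the gene of the AA4.1 antigen, was not called. Fcer2a (0.30 ± 0.09), the CD23 gene, was called with all arrays but not without replicate 2 of wild type (0.23) or replicate 1 of cko (0.20), and Ptprc (0.20 ± 0.06), the B220 gene, was not called without replicate 1 or 2 of wild type (0.19 and 0.20) or of cko (0.20 and 0.20).

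Whether other splits of the 12 arrays into 6 and 6 call as many genes as genotype was tested with time as a covariate, in 100 of the 462 possible splits. The real split called 2903 genes, the highest other split called 16, and 1 of 100, the real one, called as many. Only 3 of the splits drawn keep duplicates together and the others set arrays of the same group against each other, so this count decides nothing. Among the 10 splits that keep them together, 3 called as many genes, the real one with 2903 and a pair with 4118, of which 1 is the control-probe division. With time in the model, both of that pair compare the genotypes at 12 h alone. The splits are too few for a share under 0.05.

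Genes at least 2-fold different at all 3 times (87) were tested for a segment of another strain carried with the modified locus. Neighbouring pairs among the tested genes numbered 2, Rgs13 with Rgs1 and S100a8 with S100a9, against a mean of 0.64 in 10000 random sets (one-sided permutation p = 0.129). A segment around Zfx was excluded as the cause for 86 of the 87 genes, since 1.1% of the set lay on the chromosome of Zfx, against 3.0% of the tested genes. The bound written beforehand, that p of 0.05 or more would exclude this, was wrong, because a p that misses its threshold excludes nothing, so a segment at a modified locus elsewhere was left open. Sequence differences under single probe sets were argued against as the whole cause for the 37 genes with another probe set, since 64% of 50 other probe sets (32, 95% Wilson interval 50.1 to 75.9) were called in the same direction and 0 in the opposite one. The 50 genes without another probe set were not tested.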
